A study of Caenorhabditis elegans with 6 samples.

How the data were processed

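RNA from whole Caenorhabditis elegans of the N2 Bristol strain, the usual wild-type laboratory strain, was profiled at 2 ages, with 3 samples at day 10 and 3 at the L4 stage, the last larval stage before the adult moult. Per the labels, synchronized animals were grown untreated on nematode growth medium at 20 °C, washed at least 3 times to remove bacteria and frozen, RNA was extracted with Trizol, and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. The event from which day 10 is counted, any measure taken against progeny, and whether reads keep their strand were not given in the sources used here. Samples were grouped by the age in their titles. Nothing says that the samples of an age came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

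The deposited table of raw read counts per gene is, per the submitters' processing notes, the product of a workflow that names CASAVA 1.8, HISAT2 and HTSeq; the genome build, annotation and counting settings were not given in the sources used here. It holds 46940 features, of which 46778 carry a WormBase gene identifier and 162 are unannotated features added by the authors. The deposited FPKM values equal the counts divided by 1 gene length per feature and by the library total, to a relative difference of 9.1e-08. In the authors' deposited comparison of the ages, the group means, a signal in units of scaled counts, equal the means of the counts after division by median-of-ratios size factors, to a relative difference of 9.3e-10. That table also gives the p-values and adjusted p-values of the authors, whose test was not given in the sources used here; its column of log2 fold changes holds cells that a spreadsheet had turned into errors and was not used.

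Symbols and coordinates were taken by gene identifier from the Ensembl release 115 annotation of WBcel235 and the matching RefSeq gene table. A symbol was found for 43827 features, and 46603 features were in the annotation. Coordinates are on WBcel235, which need not be the build on which reads were counted. Genes of the mitochondrial genome were named by position for 9 genes, since their symbols differ between the tables.

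Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, as day 10 against L4, with TMM scaling, edgeR's default filter on low counts, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05; 15956 genes were tested. Levels are given as CPM, counts scaled to a common total, of the TMM-scaled library, as mean ± SD over 3 libraries. The standard error of a log2 fold change comes from the spread of log2(CPM + 0.5) within the ages. Where a group held 0 counts in its 3 libraries, the fold is a lower bound set by 3 counts over the pooled libraries of that group. Where a group held 1 to 3 counts, the ratio of pooled levels is given with its exact 95% counting interval. Such bounds and intervals cover counting error only.

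The sample groups, the tests of the report, the alternatives, the rule for named genes and 39 lists of gene families, complexes, tissues and stages were fixed before the data were examined, except for the members of the mitochondrial list. Tests that the closing section names as chosen later were not. Lists with at least 5 tested members were compared with the other genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation, fry, and the number of members that passed edgeR's test. The list of mitochondrial genes was taken as the annotated protein-coding genes of that genome, since its symbols did not match the table. The lists overlap, with 46 genes on more than 1. Genes were named by a rule: the 8 largest log2 fold changes in each direction among genes with an adjusted p under 0.05, a mean of at least 50 CPM, a symbol and no overlap between the ages, then the 2 members of each list with the highest mean CPM, then 23 fixed genes.

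The steps were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed; 15704 of the simulated genes passed the filter. For day 10 against L4, the test recovered 44% of 50 genes simulated with a 1.5-fold change and 100% of those with a 2-fold, 4-fold or 8-fold change, with 8 false calls, 4.44% of the calls. All simulated genes had a single common spread, and far fewer changed than the 85.45% called in the real data. The simulation therefore does not test the scaling, or measure recovery, where most genes move. Its changed genes were drawn above a minimum level, so recovery at low counts was not measured either.

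Alternatives were DESeq2's size factors, upper-quartile factors and library size alone in place of TMM; no filter, or at least 1 CPM in 3 libraries; fits without the robust option; removal of the 50 most abundant genes; the replicate number as a block; each library left out; DESeq2 1.42.0; limma on log2(FPKM + 1) and log2(FPKM + 0.1); edgeR's test against a 2-fold change; the authors' deposited comparison; and, for lists, camera on ranks. Major sperm protein, histone, actin, small heat-shock and vitellogenin genes have close copies, and overlapping or antisense genes may share reads, so values of single members are uncertain.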

Results

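The series compared the transcriptome of whole wild-type C. elegans at day 10 with that of L4 larvae, as a comparison of aged with young animals. It held no young adult samples. Changes from larva to adult and changes with adult age therefore cannot be told apart here. Read counts per gene were available for 3 libraries of each age. The day 10 libraries held 25616846, 25176942 and 23257607 counts, and the L4 libraries 19576201, 23972794 and 19906926. Across genes, log2 CPM correlated at 0.9858 to 0.9947 (Pearson) between day 10 libraries, at 0.9946 to 0.9962 between L4 libraries and at 0.6696 to 0.6854 between the ages. Genes are not independent replicates. No pair of libraries matched within sampling noise, and the pair of day 10 replicates 1 and 3 was the farthest apart within an age.

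Day 10 animals held far higher transcript levels of most listed oocyte, yolk, DNA replication and early embryonic genes than L4 larvae, and far lower levels of most cuticle collagen, sperm and muscle genes. All 29 tested genes of oocytes and the eggshell rose, with a median log2 fold change of 4.01, and all 30 major sperm protein genes fell, with a median of −5.16. Of 145 cuticle collagens, 113 fell, with a median of −6.71. Vitellogenin vit-2, which encodes a yolk protein made in the intestine, rose from 159 ± 64.9 to 6997 ± 1655 CPM (mean ± SD, n = 3). Muscle myosin unc-54 fell from 6337 ± 391 to 153 ± 7.92 CPM.

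Of 15956 genes tested, 13634 changed by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, which is 85.45%. Of these, 6460 were higher and 7174 lower at day 10. A change of at least 2-fold was seen for 4640 higher and 5934 lower genes, and of at least 10-fold for 1044 and 2555. The libraries of the ages did not overlap for 87.56% of genes, where chance gives 10%. The median log2 fold change over all genes was −0.16; it was 0.00 with DESeq2's size factors and −0.61 with upper-quartile factors, so small changes depend on the scaling. In the authors' deposited table, 6914 features were higher and 6685 lower at an adjusted p under 0.05.

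**Figure D1:**
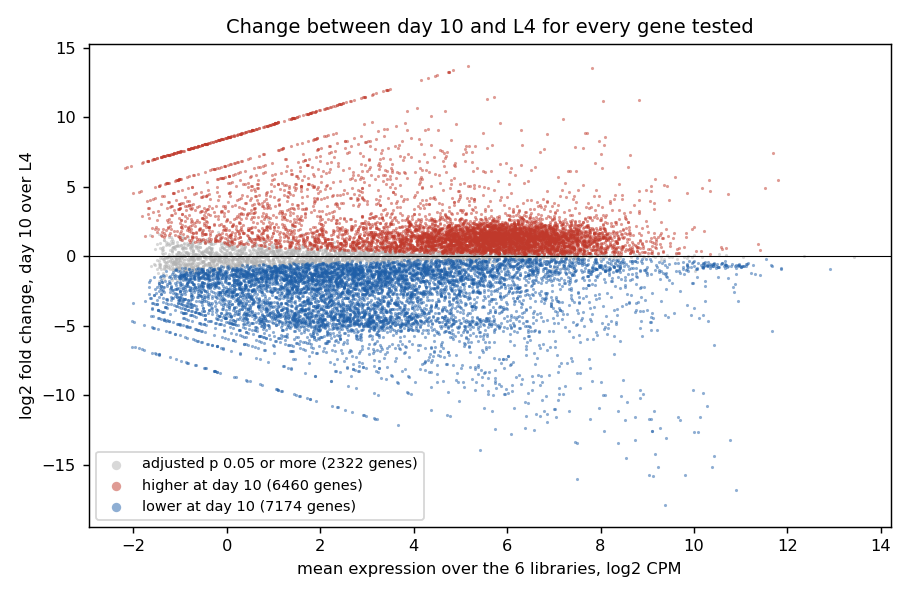
Log2 fold change of day 10 over L4 against mean log2 CPM over the 6 libraries, 1 point per gene tested. Red marks the 6460 genes higher and blue the 7174 genes lower at day 10 by edgeR's test; the slanted lines at the edges are genes with few or no counts at 1 age, whose fitted value is not a measured fold.

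Of the 8 largest falls, 6 were in cuticle collagens. The collagen col-175 (WBGene00000748, X, 9233638 to 9234618) stood at 1339 ± 26.8 CPM in L4 and had 0 counts at day 10, at least 33150-fold lower. The gene K02E11.10 (WBGene00044109, V, 14240069 to 14241151), at 360 ± 13.6 CPM in L4, also had 0 counts at day 10, at least 8919-fold lower. For col-73 (WBGene00000649, II, 4872098 to 4873129), 2 counts at day 10 against 3798 ± 72.1 CPM in L4 gave a ratio of 141100 (95% counting interval 39060 to 1165000). The collagen dpy-13 (WBGene00001074, IV, 4235614 to 4236710) fell by 15.16 on the log2 scale, from 2665 ± 62.8 to 0.0669 ± 0.0454 CPM; without day 10 replicate 1 it fell by 15.81. The other genes with the largest falls held 1 or 2 counts at day 10, all in a single library. The ratios were 82690 (95% counting interval 14840 to 3266000) for col-17, 77810 (13970 to 3073000) for sqt-1, 66330 (18360 to 547700) for rol-1 and 44660 (12360 to 368800) for col-77. The fitted log2 fold change went from −15.84 to −17.60 for col-17 without day 10 replicate 1 and from −15.75 to −17.52 for sqt-1 without replicate 2. Without replicate 3 it went from −15.75 to −18.30 for rol-1 and from −15.18 to −17.73 for col-77.

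The largest rises included a lectin, a uterine and a membrane protein gene. The C-type lectin clec-266 (WBGene00016088, X, 6617393 to 6622915) stood at 451 ± 125.9 CPM at day 10 and had 2 counts in L4, a ratio of 14180 (95% counting interval 3925 to 117100). The gene skr-7 (WBGene00004813, V, 4422427 to 4423011), a member of the family of Skp1-related ubiquitin ligase subunits, stood at 105 ± 21.2 CPM with 2 counts in L4, a ratio of 3310 (916 to 27340). Its fitted log2 fold change, 11.47, was 14.27 without L4 replicate 1, the library that held both counts, and 10.88 without L4 replicate 2, while that of clec-266 went from 13.57 to 12.98 without L4 replicate 2. The gene ule-1 (WBGene00021005, I, 2219468 to 2222313), named for expression in the uterine lumen, rose by a log2 fold change of 11.20 ± 0.20 (SE) to 911 ± 48 CPM, and cav-1 (WBGene00000301, IV, 9772510 to 9773559), a caveolin, by 11.19 ± 0.25 to 533 ± 128 CPM. The log2 fold changes of C10G8.4, spex-3, ZK813.2 and ZK813.1 were 9.89, 9.60, 9.06 and 8.85, and without L4 replicate 1 they were 10.59, 11.13, 10.34 and 10.09.

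Genes of the larval cuticle and its renewal fell as groups. Of the 145 cuticle collagens, the structural proteins of the cuticle, 113 fell and 21 rose, 134 changed when adjusted over the list alone, and the median was −6.71, or −6.60 with genes at 0 counts set to their bound, −7.37 without day 10 replicate 3 and −7.31 for genes with at least 1 CPM in 3 libraries (camera's adjusted p = 2e-47; adjusted p = 0.051 with an estimated correlation). The adult collagen col-19 stood at 47.4 ± 27.2 CPM at day 10 and 30.7 ± 14.6 in L4, a difference within the spread (edgeR's adjusted p = 0.296). Of 28 moulting factors, 22 fell and 4 rose, 26 adjusted over the list alone. Their median was −2.86 (camera's adjusted p = 7.1e-10; adjusted p = 0.18 with an estimated correlation). The gene mlt-11, a protease inhibitor, fell from 903 ± 131 to 35.1 ± 7.95 CPM, and noah-1 from 706 ± 62.3 to 72.2 ± 13.1 CPM. Of 65 hedgehog-related and patched-related genes, 54 fell and 5 rose (3 without L4 replicate 2), 59 adjusted over the list alone. These had a median of −3.59 (camera's adjusted p = 1.4e-16; adjusted p = 0.051 with an estimated correlation). Within that list qua-1 fell from 709 ± 32.8 to 1.43 ± 0.483 CPM, while ptc-1, a patched homologue used in the germ line, rose from 239 ± 5.14 to 794 ± 81.2 CPM.

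Genes of developmental timing and vulval patterning moved both ways. Of 30, 11 rose and 18 fell, 29 adjusted over the list alone, with a median of −0.91 while camera's direction was up (adjusted p = 0.89). The period homologue lin-42 fell from 672 ± 71.5 to 9.97 ± 0.956 CPM, lin-29, which drives the switch to the adult epidermis, from 52.5 ± 3.43 to 4.07 ± 0.503 CPM, and lin-14 fell by 1.74 on the log2 scale. The RNA-binding regulator lin-41, also active in oocytes, rose from 62.5 ± 1.35 to 490 ± 73.9 CPM.

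Sperm genes fell, and genes of oocytes, germ line and cell division rose. All 30 major sperm protein genes fell, 30 adjusted over the list alone. The median was −5.16, or −5.14 with bounds (camera's adjusted p = 4.8e-24; adjusted p = 0.18 with an estimated correlation). The gene msp-36 fell from 188 ± 0.973 to 4.42 ± 0.898 CPM and msp-142 from 62.4 ± 0.867 to 2.19 ± 0.665, with the caution that near-identical copies share reads. Of 58 other sperm genes, 54 fell and 3 rose, 57 adjusted over the list alone. Their median was −4.28 (camera's adjusted p = 1.8e-10; adjusted p = 0.18 with an estimated correlation), and spe-39, which also works in other tissues, was among those that rose (log2 fold change 1.30 ± 0.09). All 29 oocyte and eggshell genes rose, 29 adjusted over the list alone. Their median was 4.01 (camera's adjusted p = 9.2e-21; adjusted p = 0.31 with an estimated correlation). The eggshell proteins cbd-1 (WBGene00010351, IV, 11372991 to 11377627) and cpg-2 (WBGene00015102, III, 7102092 to 7103990) rose from 95.8 ± 12 to 2496 ± 422 CPM and from 146 ± 6.15 to 3251 ± 762 CPM. Day 10 replicate 3 was lower than replicates 1 and 2 on this list, by a median log2 difference of −0.39.

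Of 45 genes of the germ line and meiosis, 43 rose and 1 fell, 44 adjusted over the list alone. The list median was 1.33 (camera's adjusted p = 3.3e-08; adjusted p = 0.32 with an estimated correlation). The Notch receptor glp-1, which maintains germ line stem cells, rose from 74.2 ± 3.23 to 344 ± 46.2 CPM and the translational repressor gld-1 from 363 ± 9.73 to 1163 ± 98.4 CPM, while the P granule helicase glh-1 fell by 0.34 on the log2 scale. Of 50 genes of DNA replication and the cell cycle, 49 rose and none fell, 50 changing when adjusted over the list alone. These had a median of 2.15 (camera's adjusted p = 4.8e-24; adjusted p = 0.051 with an estimated correlation), and cyclin cyb-3 rose from 73.3 ± 1.48 to 1052 ± 34 CPM. Of 34 early embryonic zygotic genes in the count table, 25 were tested. Of these 25, 20 rose and 4 fell, 24 adjusted over the list alone. The median was 3.44, or 5.02 without L4 replicate 3 (camera's adjusted p = 0.003; adjusted p = 0.34 with an estimated correlation). For the 21 genes with at least 1 CPM in 3 libraries, the median was 2.88, with 16 higher and 4 lower. Any member with almost no counts in L4 could pass the filter on low counts only through day 10. Within the list pal-1, a caudal homologue, rose from 15.8 ± 1.67 to 118 ± 12 CPM. All 42 RNA splicing genes rose, 42 adjusted over the list alone. Their median was 1.20 (camera's adjusted p = 7.5e-09; adjusted p = 0.27 with an estimated correlation), with hrpa-1 and prp-8 at log2 fold changes of 1.26 ± 0.05 and 1.11 ± 0.06. Of 72 histone genes in the count table, only 36 were tested, at a median of 1.52 CPM at day 10. Of these 36, 12 rose and 15 fell, 27 adjusted over the list alone. The median was −0.09, and 0.07 with DESeq2's size factors, while camera's direction was up (adjusted p = 0.83). The H3.3 variant his-72 rose by 1.55 ± 0.10.

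All 6 vitellogenins rose, 6 adjusted over the list alone, with a median of 4.35, though the list did not pass camera (adjusted p = 0.11). It did pass without a filter on low counts (0.0459), with camera on ranks (0.0403) and without L4 replicate 1 (0.0042), among other settings. Without the 50 most abundant genes, 3 members stayed in the list, with a median of 2.67. Besides vit-2, the abundant members vit-5 and vit-6 rose from 39.1 ± 29.1 to 6581 ± 2001 CPM and from 194 ± 72.7 to 5690 ± 1720 CPM. The log2 fold change of vit-5 was 7.40, and 8.20 without L4 replicate 1, which held 72.7 CPM against 21.3 and 23.3 in the other L4 libraries.

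**Figure D2:**
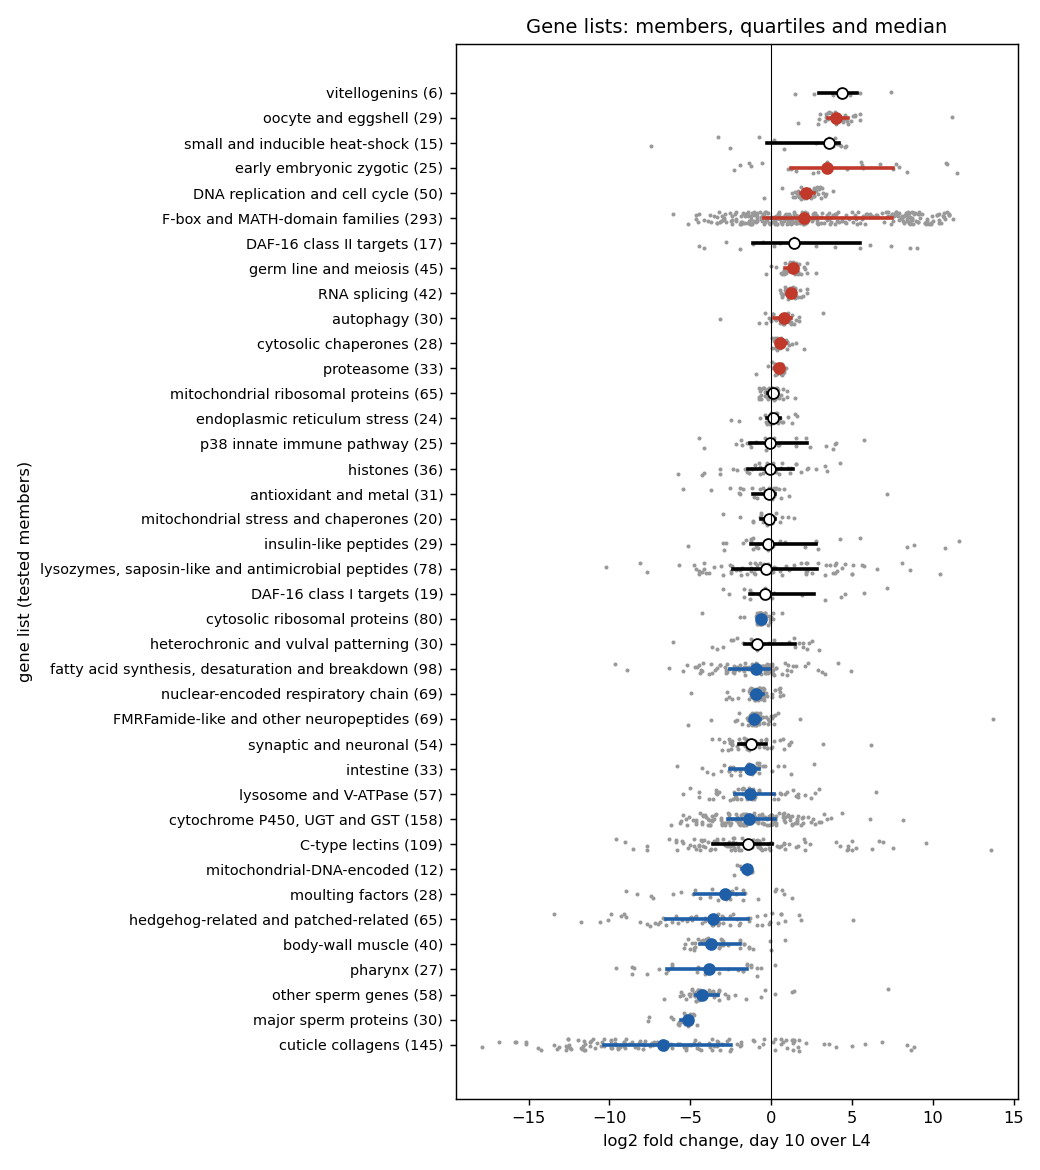
Log2 fold change of day 10 over L4 for the members of 39 gene lists, with the number of tested members in brackets. Grey points are genes, bars run from the lower to the upper quartile and circles are medians; red and blue mark the 9 lists shifted up and the 15 shifted down by camera with the preset correlation, and open black circles the others. With upper-quartile factors the medians of mitochondrial ribosomal proteins and endoplasmic reticulum stress genes are below 0 and that of the proteasome is at 0.00; with DESeq2's size factors those of histone, p38, antioxidant and mitochondrial stress genes are above 0.

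The muscle and pharynx lists had lower medians than the neuronal and intestinal lists. Of 40 body-wall muscle genes, 37 fell and 1 rose, 38 adjusted over the list alone. Their median was −3.71 (camera's adjusted p = 3.5e-20; adjusted p = 0.051 with an estimated correlation). Besides unc-54 (WBGene00006789, I, 14855901 to 14863482), actin act-4 fell from 3577 ± 135 to 385 ± 41.9 CPM. Of 27 pharynx genes, 25 fell and none rose, 25 adjusted over the list alone. The list median was −3.86 (camera's adjusted p = 1.5e-08; adjusted p = 0.052 with an estimated correlation), and the pharyngeal myosin myo-1 fell from 277 ± 19 to 12.2 ± 0.107 CPM. Of 33 intestine genes, 26 fell and 4 rose, 30 adjusted over the list alone. Their median was −1.29 (camera's adjusted p = 0.0031; adjusted p = 0.34 with an estimated correlation). The protease asp-1 fell from 3028 ± 99.2 to 640 ± 163 CPM, and elt-2, the main intestinal GATA factor, from 13.8 ± 1.90 to 7.50 ± 1.30. Of 54 synaptic and neuronal genes, 38 fell and 8 rose, 46 adjusted over the list alone (median −1.26), and the list did not pass camera (adjusted p = 0.064), though it did without a filter on low counts (0.00988) and with camera on ranks (0.00644). Synaptobrevin snb-1 and tyrosine decarboxylase tdc-1, which also serves gonadal cells, rose by 0.78 ± 0.04 and 3.19 ± 0.16. Of 69 neuropeptide genes, 56 fell and 3 rose, 59 adjusted over the list alone. These had a median of −1.04 (camera's adjusted p = 0.036, and 0.0587 without day 10 replicate 1; adjusted p = 0.65 with an estimated correlation). The neuropeptide nlp-24 fell from 124 ± 7.32 to 3.50 ± 0.707 CPM.

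Cytosolic ribosomal proteins and respiratory chain genes were lower at day 10. Of 80 cytosolic ribosomal proteins, 72 fell and 1 rose, 74 adjusted over the list alone. Their median was −0.66 (camera's adjusted p = 0.0019; adjusted p = 0.65 with an estimated correlation), with rpl-3 at −0.87 ± 0.08. Of 69 nuclear-encoded respiratory chain genes, 60 fell and 5 rose, 65 adjusted over the list alone. Their median was −0.96 (camera's adjusted p = 6.6e-06; adjusted p = 0.32 with an estimated correlation), and the ATP synthase subunit atp-2 fell from 3904 ± 94.7 to 1550 ± 162 CPM. All 12 protein-coding genes of the mitochondrial genome fell, 12 adjusted over the list alone. The list median was −1.51 (camera's adjusted p = 0.0012; adjusted p = 0.4 with an estimated correlation), and COX1 (WBGene00010964, mitochondrial genome, 7827 to 9428) fell from 3574 ± 42.9 to 1463 ± 106 CPM. Of 65 mitochondrial ribosomal proteins, 24 rose and 15 fell, 38 adjusted over the list alone, with a median of 0.11 (camera's adjusted p = 0.67). With upper-quartile factors 5 rose and 44 fell, with a median of −0.34, and with DESeq2's size factors 39 rose and 10 fell.

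The mixed list of small and inducible heat-shock genes was split. Most cytosolic chaperones rose slightly under the main scaling but not with upper-quartile factors. Of 15 small and inducible heat-shock genes, 9 rose and 4 fell, 13 adjusted over the list alone, with a median of 3.60 and camera's adjusted p = 0.5. The small heat-shock gene hsp-16.2 (WBGene00002016, V, 1804334 to 1804957) rose from 1.64 ± 0.609 to 30.6 ± 16.8 CPM and sip-1, known from oocytes and embryos, from 76.1 ± 1.54 to 1778 ± 294 CPM, while hsp-25 fell from 112.2 ± 1.84 to 19.6 ± 2.33 CPM. The genes hsp-16.41, hsp-16.48, hsp-70, F44E5.4 and F44E5.5 also rose, by log2 fold changes of 3.60 to 4.62, though hsp-16.48 reached only 1.02 CPM. Besides hsp-25, the genes that fell were hsp-12.1, hsp-12.2 and hsp-17. The heat-shock regulator hsf-1 rose by 2.0 ± 0.03. Of 28 cytosolic chaperones, 26 rose and none fell, 26 adjusted over the list alone. These had a median of 0.54 (camera's adjusted p = 0.0079; adjusted p = 0.28 with an estimated correlation), but with upper-quartile factors 10 rose, 5 fell and the list did not pass (adjusted p = 0.0685). Within it hsp-90 rose by 0.90 ± 0.02, and hsp-1 by 0.43 ± 0.07, a sign that turned to −0.024 with those factors.

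Of 33 proteasome genes, 29 rose and 2 fell, 31 adjusted over the list alone. Their median was 0.45 (camera's adjusted p = 0.038; adjusted p = 0.72 with an estimated correlation). With upper-quartile factors the median was 0.00, where 14 rose and 11 fell, and camera's adjusted p was 0.0574 without day 10 replicate 1 and 0.0536 without replicate 2. It was 0.0507 for genes with at least 1 CPM in 3 libraries. Of 30 autophagy genes, 22 rose and 4 fell, 26 adjusted over the list alone. Their median was 0.82 (camera's adjusted p = 0.02, and 0.0685 with upper-quartile factors; adjusted p = 0.44 with an estimated correlation), and the receptor sqst-1 rose by 1.07 ± 0.11. With upper-quartile factors 17 autophagy genes rose and 9 fell, and with DESeq2's size factors 24 and 2. Of 20 mitochondrial stress genes, 6 rose and 10 fell, 16 adjusted over the list alone; the median was −0.15, and 0.01 with DESeq2's size factors (camera's adjusted p = 0.82). With upper-quartile factors 3 rose and 16 fell. The chaperone hsp-60 fell by 1.12 on the log2 scale and hsp-6 stood at 867 ± 106 and 905 ± 12.9 CPM at day 10 and in L4 (edgeR's adjusted p = 0.521), though with upper-quartile factors it was lower, at −0.513. Of 24 endoplasmic reticulum stress genes, 11 rose and 7 fell, 18 adjusted over the list alone, with a median of 0.08 (camera's adjusted p = 0.67), but with upper-quartile factors 6 rose and 14 fell, with a median of −0.37. The disulfide isomerase pdi-2 fell from 3011 ± 132 to 745 ± 48.4 CPM, and hsp-4 rose by 0.33 ± 0.07, or −0.119 with those factors.

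Immune, detoxification and stress-resistance lists held members that moved far in both directions. Of 109 C-type lectins, 24 rose and 70 fell, 94 adjusted over the list alone. The list median was −1.45 (camera's adjusted p = 0.09, and 0.0129 on ranks), with clec-87 up from 41.4 ± 3.26 to 1334 ± 63.3 CPM and clec-63 down from 1603 ± 10.1 to 411 ± 179 CPM. Of 78 lysozymes, saposin-like and antimicrobial genes, 30 rose and 33 fell, 63 adjusted over the list alone, with a median of −0.34, a mean of 0.12 and camera's adjusted p = 0.57. The lysozyme lys-7 rose from 29 ± 1.57 to 1516 ± 703 CPM, and irg-7 fell from 771 ± 25.6 to 169 ± 93.9. Of 25 genes of the p38 immune pathway, 12 rose and 10 fell, 22 adjusted over the list alone; the median was −0.05, with a mean of 0.37, a median of 0.11 with DESeq2's size factors, and camera's direction up (adjusted p = 0.82). Day 10 replicate 3 lay below replicates 1 and 2 on the p38 list, with a median log2 difference of −0.74, and on the lysozyme list, with −0.42. Of 158 cytochrome P450, UGT and GST genes, 94 fell and 32 rose, 126 adjusted over the list alone. Their median was −1.36 (camera's adjusted p = 0.022, and 0.0646 with upper-quartile factors; adjusted p = 0.61 with an estimated correlation). The abundant gst-7 rose by 1.65 ± 0.13, and gst-4 fell by 2.65 on the log2 scale. Without day 10 replicate 1 it fell by 3.31.

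Of 19 class I targets of DAF-16, the FOXO factor of insulin signalling, 6 rose and 7 fell, 13 adjusted over the list alone; the median was −0.40 while the mean was 0.67 and camera's direction up (adjusted p = 0.82). Day 10 replicate 3 lay below the other day 10 libraries on this list, with a median log2 difference of −1.08. The metallothionein mtl-1 rose from 0.357 ± 0.145 to 51.4 ± 25 CPM, the superoxide dismutase sod-3 fell from 1.86 ± 0.123 to 0.819 ± 0.256 CPM, and icl-1 of the glyoxylate cycle fell from 3166 ± 121 to 525 ± 275. Of 17 class II targets, 10 rose and 4 fell, 14 adjusted over the list alone. These had a median of 1.38 (camera's adjusted p = 0.36), or 0.52 over the 15 members left without the 50 most abundant genes, and daf-16 itself rose by 0.79 ± 0.05. Of 29 insulin-like peptides, 10 rose and 13 fell, 23 adjusted over the list alone; the median was −0.18, the mean 1.25 and camera's direction up (adjusted p = 0.71), and ins-27 fell by 2.93 on the log2 scale. Of 31 antioxidant and metal genes, 6 rose and 13 fell, 19 adjusted over the list alone; the median was −0.11, and 0.06 with DESeq2's size factors (camera's adjusted p = 0.54). With those factors 11 rose and 13 fell, and with upper-quartile factors 1 rose and 21 fell. Ferritin ftn-2 fell by 1.72 on the log2 scale, and ftn-1 stood at 36.4 ± 14.6 and 47.9 ± 3.05 CPM at day 10 and in L4 (edgeR's adjusted p = 0.278), though with upper-quartile factors it was lower at day 10, at −0.851.

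Of 98 fatty acid genes, 61 fell and 15 rose, 73 adjusted over the list alone. Their median was −0.94 (camera's adjusted p = 0.0046; adjusted p = 0.61 with an estimated correlation), and the acyl-CoA dehydrogenase acdh-1 (WBGene00016943, I, 6497436 to 6499560) fell from 2025 ± 82.4 to 2.52 ± 1.64 CPM. Of 57 lysosome and V-ATPase genes, 40 fell and 14 rose, 54 adjusted over the list alone. Their median was −1.33 (camera's adjusted p = 0.0052; adjusted p = 0.65 with an estimated correlation). The abundant member asp-6 stood at 1589 ± 427 and 1398 ± 31.6 CPM (edgeR's adjusted p = 0.403) and was higher at day 10 without day 10 replicate 3, at a log2 fold change of 0.391. Of 293 genes of the F-box and MATH-domain families, many of which encode adaptors of ubiquitin ligases, 188 rose and 67 fell, 255 adjusted over the list alone. The list median was 2.02 (camera's adjusted p = 0.00057; adjusted p = 0.44 with an estimated correlation), with bath-42 up from 79.2 ± 0.279 to 344 ± 4.05 CPM. The list holds 61 fbxb genes with 0 counts in L4, which could pass the filter on low counts only through day 10. Genes often used as references also moved: act-1 fell from 565 ± 14.7 to 114 ± 8.39 CPM, while pmp-3 rose by 1.49 ± 0.04 and cdc-42 by 0.89 ± 0.05, each keeping its sign under every scaling run.

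**Figure D3:**
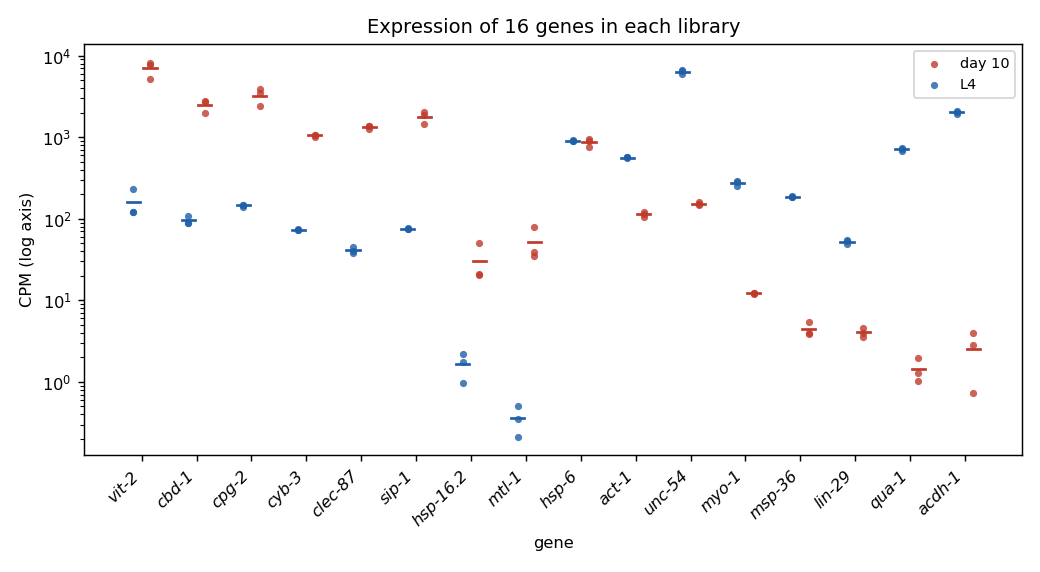
Expression of 16 genes in each of the 6 libraries, in CPM on a log axis, with day 10 in red and L4 in blue; points are libraries and lines the means of 3. The yolk gene vit-2 stands at 6997 CPM at day 10 and 159 in L4 and the myosin unc-54 at 153 and 6337, while hsp-6 stands at 867 and 905; with upper-quartile factors hsp-6 is lower at day 10.

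In total, 24 of 39 lists shifted by camera with the preset correlation, 9 up and 15 down, and 0 did so with an estimated correlation. With upper-quartile factors the rises numbered 1 among moulting factors, 3 among hedgehog-related genes, 1 among respiratory chain genes, 2 among intestine genes and 5 among neuronal genes. By fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, 34 lists passed. Splits of the 6 libraries that mix the ages, each of which keeps part of the age difference, gave 24 to 29 shifted lists and 0 changed genes. The real grouping gave no more shifted lists than these, so that number does not set it apart from mixed groupings.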

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

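No test in this part was chosen after its result was seen. The number of changed genes, 13634, stayed within 1.5 times of that value under the alternatives run, from 9242 when tested against a 2-fold change to 14401 without a filter, and from 13061 to 13949 with a library left out. With a library left out, genes higher ran from 6228 to 6584, genes lower from 6818 to 7365, genes changed at least 2-fold from 10422 to 10616, and shifted lists from 22 to 25. Upper-quartile factors moved the split most, to 5301 higher and 8408 lower, with 139 of the calls reversed; no call reversed under the other alternatives. Those factors turned the sign of hsp-1 (−0.024), nlp-40 (−0.024) and hsp-4 (−0.119), which follows from the lower median of all genes they give, and ended the calls of lgg-1 and math-33. Of 107 named genes, 97 kept direction and side of the threshold under all alternatives run for them. No list passed with an estimated correlation, where 0 of 39 were shifted against 24, and the cause was not tested; 34 passed fry, which does not compare a list with other genes. Without that setting, 24 of the 39 lists never changed their call. Replicate numbers paired the samples weakly if at all. Between the ages, deviations of same-numbered libraries correlated at 0.02, 0.019 and 0.019, below 0.1, and those of differently numbered libraries at −0.016 to −0.005. The replicate block gave 13397 changed genes and 25 shifted lists, adding the vitellogenins (camera's adjusted p = 0.0115). The authors' deposited comparison shared 12860 of the 13634 calls in the same direction. Depth limits what can be said of genes near 3 counts. In counts simulated at the depth, spread and 3 libraries per age seen here, 44% of 1.5-fold changes were recovered.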

Other observations

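The tests of gene symbol families, chromosomes and gene length, of hatched larvae, of even dilution and of a few genes taking most of the counts, and of the share of intestinal RNA and the depth of day 10 replicate 3 were chosen only after the results were seen.

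Among 144 families of genes that share a symbol stem, with at least 10 tested members, 45 passed camera, 24 up and 21 down, and 0 did so with an estimated correlation. In the F-box family fbxb, 89 of 90 tested members rose and none fell, at a median of 2.39 CPM at day 10. Of the 90, 61 had 0 counts in L4. These could pass the filter on low counts only through day 10, so their direction was fixed once tested. The family's median log2 fold change was 8.28 as fitted and 5.37 with those 61 genes at their bound. Its camera values rest in part on them (camera's adjusted p = 4.4e-07, and adjusted p = 0.68 with an estimated correlation). The sdz family, named for control by the embryonic factor SKN-1, had 21 of 23 higher (median with bounds 5.68), and T-box factors (tbx) 12 of 15 (median with bounds 5.02). The same limit holds for the 11 sdz and 6 tbx genes with 0 counts in L4. Nuclear pore proteins (npp) rose in 25 of 26 genes with a median of 1.61, Mediator subunits (mdt) in 19 of 20 with 1.55, TFIID subunits and related factors (taf) in 16 of 17 with 1.69, and the ced genes, many of which act in cell death and corpse removal, in 12 of 12 with 1.57. Neprilysin-like proteases (nep) fell in 20 of 21 genes, with a median of −4.2, and aldehyde dehydrogenases (alh) in 11 of 12, with −1.29.

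The 21 cuticle collagens that went against their list included dpy-14, at 68.1 ± 9.92 CPM at day 10 and 0.592 ± 0.0746 in L4 (mean ± SD, n = 3), col-95, at 89.6 ± 29.6 and 0.195 ± 0.187, and col-119, at 207 ± 31.9 and 17.2 ± 11.4; these were chosen after their values were seen. Genes of the X chromosome had a median log2 fold change of −0.89 over 2122 protein-coding genes, of which 57.2% fell and 25.4% rose. Camera's adjusted p was 0.018 with the preset correlation, and an estimated correlation was not run for chromosomes. Autosomes had medians from −0.49 to 0.34. Among genes of the muscle, pharynx, intestine, neuronal and neuropeptide lists, the medians were −1.33 for 64 genes on X and −1.35 for 158 on autosomes. Gene length correlated weakly with the log2 fold change across genes (Spearman 0.07), and in 4 equal groups by length the medians were −0.53, −0.24, −0.22 and 0.22 from shortest to longest; genes are not independent replicates.

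The rise of early embryonic zygotic genes may come from embryos inside or laid by the day 10 animals, since a separate set of 14 genes known from embryos, written before the test, had 12 tested members, of which 8 rose and 3 fell, with a median log2 fold change of 2.25, also with bounds (camera's p = 0.037; p = 0.19 with an estimated correlation). The hatching enzyme hch-1 stood at 54.3 ± 8.85 CPM at day 10 with 0 counts in L4, at least 1140-fold higher, whereas the Hox genes nob-1 and php-3 fell by 0.78 and 0.86 on the log2 scale. The 2 members with 0 counts in L4, hch-1 among them, could pass the filter on low counts only through day 10. Hatched larvae in moult were set against 8 collagens made at each moult, whose median at day 10 was 0.229% of the L4 level, with the 4 most abundant in L4 (dpy-13, sqt-1, rol-6 and dpy-8) at 0.00129% to 0.0509% but dpy-10, dpy-2 and dpy-3 at 4.58%, 1.25% and 1.07%. A first criterion, under 1% for all 8, left the test undecided. A second asked this only of the median and those 4 genes, and was met. It was set after the values were seen and rests on the genes with the lowest percentages, so it cannot decide. The values show only that transcripts of those 4 genes were nearly absent at day 10, and larvae in moult stay undecided as a source. Larvae that are not moulting, old oocytes that transcribe embryonic genes, and age itself, stay open as untested.

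The fall of tissue genes at day 10 was unequal, with medians of −3.71 for 40 muscle genes and −1.26 for 54 neuronal genes. A few genes taking most of the counts would lower both lists alike. The 10 most abundant genes of each library held 4.704% to 5.636% of its counts at day 10 and 5.654% to 5.963% in L4. The medians and these shares argue against that cause. Dilution of somatic RNA by germ line and embryo RNA would lower both lists alike only if those tissues held no transcripts of either list. That was not checked. Of the neuronal genes 8 rose, against 1 of the muscle genes, and tdc-1, which also serves gonadal cells, rose by 3.19. Such dilution could therefore not be excluded. The medians differed by −2.45 (permutation of genes between the lists, two-sided, p = 1e-04, the smallest they can give), though the permutation takes genes as independent, which they are not. It tests the same difference that prompted it, so it does not tell causes apart. In single libraries, the median deviation of muscle genes from their mean over the 6 libraries lay below that of neuronal genes by a difference of −1.40 to −1.12 at day 10, and above it by 1.23 to 1.30 in L4. The opposite signs follow from that centring, so only the narrow range within each age adds to the medians. An uneven dilution, a lower need for muscle proteins after growth ends, and loss of muscle with age may each contribute and were not tested.

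Day 10 replicate 3 stood apart from replicates 1 and 2. Relative to them, 9 of 39 lists lay above and 13 below by over 2 standard errors of their median, and 6 of these 9 and 13 of these 13 by more than replicates 1 and 2 differed. Over genes at 1 CPM or more, class I targets of DAF-16 were lowest, with a median log2 difference of −1.12, and major sperm proteins highest, with 0.29, although replicates 1 and 2 differed there by −0.37. A smaller share of intestinal RNA could not be excluded: immune genes had a median of −0.51 and other intestinal genes −0.24, a difference of −0.27 (permutation, two-sided, p = 0.39). For lower depth, 8 lists, 6 below and 2 above, lay over 2 standard errors beyond −0.13. That value is the log2 ratio of the total count of replicate 3 to the mean of the other 2, and the most that depth would give unscaled. The levels were already scaled for depth, so such an outcome was likely beforehand. The standard errors also take genes as independent, which they are not. These values therefore show only that 8 lists lay further out than unscaled depth would put them. Other effects of depth, smaller deviations and the state of that sample stay open.

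Other splits of the 6 samples into 3 and 3 number 10 with the real one, too few for a share under 0.05. Only 1 split, the real one, gave 13634 changed genes, with 0 as the highest of the others, and likewise 1 for changes of at least 2-fold, with 10574 against 0. For lists, 10 of 10 splits gave at least 24 shifted lists, with 29 as the highest of the others. The number of shifted lists therefore does not set the real split apart. Each other split keeps part of the age difference, since it sets 2 libraries of an age and 1 of the other against the rest.

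L4 replicate 1 stood above the other L4 libraries for some genes known from adults: vit-2 at 234 CPM against 122.8 and 120, col-20 at 77.0 against 34.7 and 32.3, and ule-5 at 3.60 against 0.64 and 0.80; these genes were chosen after their values were seen.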
